A study of Drosophila melanogaster with 9 samples.

How the data were processed

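Hi-C, which joins and sequences DNA ends that lay near each other in fixed nuclei, was carried out on Kc167 cells, a Drosophila melanogaster line derived from embryos. Per the labels, cells were grown at 25 °C, brought to 37 °C for 20 min and then fixed with formaldehyde, and chromatin was cut with HindIII. The series holds 9 samples: 2 Hi-C libraries of heat-shocked cells, 5 ChIP-seq libraries of heat-shocked cells (antibodies against BEAF, CP190, CTCF, SuHw and RNA polymerase II), 1 RNA polymerase II ChIP-seq library of cells in normal culture and 1 ChIP input. The 7 ChIP and input libraries were not analysed here. The data used were 2 lists of interacting bin pairs.

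Each deposited list gives, per line, a chromosome arm, the start and end of 2 bins of 10 kb, and a score. The authors' score was negative in every line and never above -2 in either list, so both lists hold only pairs past a limit of -2. Its form is that of the logarithm of a p-value, but the base, the test and the background model behind it are not given in the sources used here, and it is not known whether the scores of the lists are on the same scale. It was used to rank pairs within a list, and values of both lists are printed as deposited. The labels of both heat-shock Hi-C libraries point to one of the lists, which therefore covers these 2 libraries together. Whether their reads were pooled before the pairs were called is not given in the sources used here. The list that covers both is called the heat-shock list. The other list is called the companion list: no label used here ties it to a sample, a condition or a number of libraries, and it was compared with the heat-shock list without assuming any of these. Bowtie 0.12.7 is named in the submitters' processing notes. The genome build is not given in the sources used here. The gene table at hand is of Release 6, and on each of the 5 arms its last gene lies past the last bin of the lists, by over 3 Mb on 3 arms. No gene was therefore assigned to a bin, the planned comparisons of gene lists and of gene density were not run, and positions are those of the deposited lists, counted from 1.

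Neither list holds a duplicate line, a pair between arms, or a pair of the same or adjacent bins; the smallest distance between bin starts was 20 kb. The only arms in the lists were 2L, 2R, 3L, 3R and X. The lists carry no read counts, so the sequencing depth and the contact frequency behind each pair are unknown, and a pair missing from a list is only known not to have passed the limit there. With 1 list of each kind there is no replicate spread, and no test between the lists was possible. Leaving out 1 library in turn was not possible for the same reason. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals, those on medians come from order statistics, and those on ratios of 2 numbers of pairs are exact conditional binomial intervals. All of them cover counting error only and treat pairs as independent, which neighbouring pairs are not, so they are narrower than the spread between cultures would be.

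Distance was taken between bin starts and divided into 5 bands. A pair was called shared when both of its bins were the same in both lists. The number expected by chance came from 1000 rotations, in which each arm of the heat-shock list was shifted by a random offset with its end joined to its start, which keeps most distances and the clustering of pairs. Partners of a bin are the different bins it is paired with in a list. For bins, Spearman's rho is given across bins, which are not independent replicates. Named regions followed a rule set before the data were examined: the 5 bins with most partners in each list, the 5 with the largest gain and the 5 with the largest loss of partners between the lists, and the 5 strongest pairs over 1 Mb apart in each list. Pairs between arms, also in that rule, do not occur. The comparison of bins in the top 1% by partners and the windows at the arm ends were chosen after the data were seen.

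Alternatives set before the data were examined were stricter lists (the strongest 50% of each), lists of equal length (the 33978 strongest heat-shock pairs against all companion pairs), overlap within 1 or 2 bins, random placement of pairs at the same distances, bins of 50 kb, partners over 1 Mb away, and pairs over 50 kb apart. Other alternatives were added after the data were seen. These were leaving out the bins in the top 1%, leaving out the centromere ends, and an expectation based on each bin's number of partners. Another was 100 random draws of as many heat-shock pairs as the companion list holds. The overlap functions were tested on simulated lists. In lists of 32506 and 49134 pairs with 9939 pairs planted in both, 10733 shared pairs were found, against a rotation mean of 1415. In independent lists of 32498 and 48778 pairs, 1387 were found against a rotation mean of 1420 and 1296 expected from partner numbers. The independent lists were drawn without bins rich in partners, unlike the real lists. The simulation therefore checks the functions and does not show that rotation gives the right chance level for the real lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.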

Results

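Interactions within chromosome arms were compared between 2 lists of paired 10 kb bins from Hi-C. The heat-shock list covers 2 libraries together from Kc167 cells, an embryonic Drosophila melanogaster line, held at 37 °C for 20 min. It held 59303 pairs that joined 10846 different bins. The companion list, whose cells and treatment no label used here gives, held 33978 pairs that joined 9895 bins. The lists carry no read counts, so the depth of each library is unknown, and neither list has replicates. Differences below describe these 2 lists, and intervals cover counting error only.

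The first comparison addressed how far apart the interacting regions lay. The title of the series speaks of a remodelling of chromosome domains by temperature. Distance between listed bins does not measure domains, and no label used here gives a temperature for the companion list. The heat-shock list was shifted to pairs between 1 and 5 Mb apart. The median distance was 1.62 Mb (95% interval 1.60 to 1.64 Mb) in the heat-shock list and 1.16 Mb (1.14 to 1.19 Mb) in the companion list. Pairs over 1 and up to 5 Mb apart made up 47.8% (47.4 to 48.2%) of the heat-shock list and 36.6% (36.0 to 37.1%) of the companion list. Pairs over 200 kb and up to 1 Mb apart made up 28.7% (28.3 to 29.0%) and 38.1% (37.6 to 38.6%), respectively. The share of pairs over 5 Mb apart was 16.8% (16.5 to 17.1%) in the heat-shock list and 17.1% (16.7 to 17.5%) in the companion list, a difference within the counting error. The share up to 50 kb apart was 1.46% (1.36 to 1.55%) against 1.31% (1.19 to 1.44%), with overlapping intervals.

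Counted as numbers of pairs, every distance band was larger in the heat-shock list. The ratio of heat-shock to companion pairs was 2.28 (2.24 to 2.33) over 1 to 5 Mb and 1.31 (1.28 to 1.34) over 200 kb to 1 Mb, against 1.75 (1.72 to 1.77) for all pairs. The longer median distance was present on all 5 arms. On 2R it was 1.5 Mb (1.46 to 1.54 Mb) in the heat-shock list against 0.97 Mb (0.94 to 1.01 Mb) in the companion list, and on 3R 1.81 Mb (1.77 to 1.86 Mb) against 1.20 Mb (1.16 to 1.26 Mb). The X chromosome had the shortest median in the heat-shock list, 1.34 Mb (1.30 to 1.39 Mb), against 1.07 Mb (1.00 to 1.13 Mb).

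**Figure D1:**
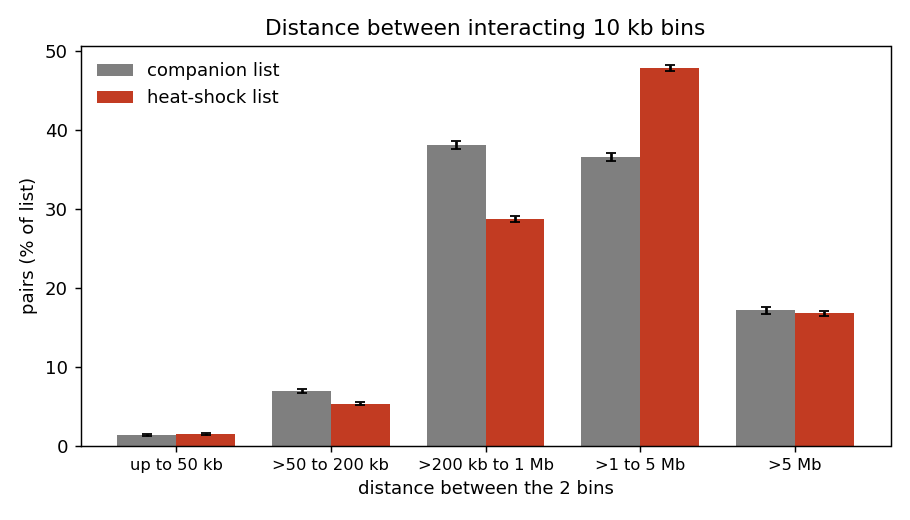
Share of listed pairs (y axis, % of the list) in 5 bands of distance between the 2 bins (x axis) for the companion list (grey) and the heat-shock list (red); error bars are exact 95% binomial intervals. The heat-shock list has 47.8% of its pairs over 1 to 5 Mb apart and the companion list 36.6%.

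The second comparison asked how many interactions the lists had in common. Of the companion pairs, 10937 were also in the heat-shock list, which is 32.2% (31.7 to 32.7%) of the companion list and 18.4% (18.1 to 18.8%) of the heat-shock list. Rotating the arms gave a mean of 397 shared pairs and at most 2075 in 1000 rotations, so the observed number was 27.5 times the mean and above every rotation. From each bin's number of heat-shock partners in each distance band, 4661 shared pairs were expected. The observed number was 2.35 times that. This expectation takes no account of distance within a band, which may make it too low. Shared pairs were short, with a median distance of 0.66 Mb (0.65 to 0.68 Mb). Pairs in the companion list alone had a median of 1.75 Mb (1.71 to 1.79 Mb) and pairs in the heat-shock list alone 1.95 Mb (1.93 to 1.98 Mb). The shared part of the companion list was 61.1% (56.4 to 65.7%) up to 50 kb, 45.1% (44.2 to 45.9%) over 200 kb to 1 Mb, 24.2% (23.4 to 24.9%) over 1 to 5 Mb and 11.2% (10.4 to 12.1%) over 5 Mb. Relative to rotation it was not lowest at the longest distances. Against the mean of 100 rotations, sharing was 31.3 times as frequent up to 50 kb, 29.1 times over 50 to 200 kb and 25.8 times over 200 kb to 1 Mb. It was 30.6 times as frequent over 1 to 5 Mb and 77.6 times over 5 Mb, where the rotation mean was only 8.42 pairs. Rotation moves bins rich in partners off their places. It also changes the distance of pairs that cross the joined ends, as long pairs more often do. The expectation from partner numbers was not split by band, so these ratios do not show which band shared most relative to chance.

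Stronger pairs were more often shared. In the companion list 50.8% of the strongest 10% by score and 18.2% of the weakest 10% were in the heat-shock list. In the heat-shock list 41.7% of the strongest 10% and 9.21% of the weakest 10% were in the companion list. Across the shared pairs, which are not independent replicates, the scores had a Spearman rho of 0.45. The median score was -2.60 in the heat-shock list and -2.59 in the companion list. A score of -10 or below was given to 751 companion pairs (2.21%) and 386 heat-shock pairs (0.651%), but it is not known whether scores of the lists are on the same scale.

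Among pairs over 1 Mb apart, the strongest in the heat-shock list joined 2L 6190001-6200000 to 2L 18450001-18460000, 12.26 Mb apart, with a score of -85.3; it was the sixth strongest in the companion list, with -178. The next joined 2L 17980001-17990000 to 2L 21610001-21620000, with -77.5 in the heat-shock list and -103 in the companion list. The third, 3R 4030001-4040000 with 3R 27230001-27240000, spanned 23.2 Mb, scored -77.0 in the heat-shock list and -9.09 in the companion list. The fourth joined 3L 22730001-22740000 to 3L 24240001-24250000 and scored -55.6 in the heat-shock list and -200 in the companion list, where it ranked second. The fifth joined 2R 11780001-11790000 to 2R 18480001-18490000, with -54.8 and -74.6. The strongest companion pair, 3L 10360001-10370000 with 3L 19550001-19560000, scored -269 there and -22.4 in the heat-shock list, and the third, 2R 9020001-9030000 with 2R 17930001-17940000, scored -192 and -20.8. Of the 5 strongest companion pairs, 2 were not in the heat-shock list. They joined 3L 16510001-16520000 to 3L 24290001-24300000, with a score of -186, and X 13680001-13690000 to X 21790001-21800000, with -181.

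The third comparison looked for regions that gained or lost partners. Of the 11120 bins used in either list, 7876 (70.8%) had more partners in the heat-shock list, 2276 (20.5%) had fewer and 968 had the same number. The median bin had 6 partners in the heat-shock list and 3 in the companion list, and the numbers were related across bins (Spearman rho 0.67). Partners were more concentrated in the heat-shock list: 111 bins had 100 or more partners there, against 3 in the companion list. That count depends on list length: there were 59 such bins among the strongest heat-shock pairs, as many as the companion list holds, and 20.7 on average (15 to 25) in random draws of that size. The 112 bins in the top 1% touched 27.2% (26.9 to 27.6%) of heat-shock pairs, and as many top bins of the companion list touched 17.8% (17.4 to 18.2%) of its pairs; with bins of 50 kb these shares were 9.0% and 7.58%. These sets had 32 bins in common, where independent sets of that size would share 1.13. The bins next to top bins had far fewer partners: the median was 134 for heat-shock top bins and 4 for the bins beside them, and 52 and 8 in the companion list, where the median bin had 3.

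The bin with most partners in both lists was 3L 24160001-24170000, 0.37 Mb from the last bin at the centromere end of its arm, with 367 partners in the heat-shock list and 295 in the companion list, at a median distance of 13.56 and 12.86 Mb. The largest gain was at 3R 6970001-6980000, from 64 partners in the companion list to 363 in the heat-shock list, where 60.1% of its partners lay over 1 to 5 Mb away and the median distance was 2.67 Mb. The bin 2R 20500001-20510000 followed, with 65 and 249 partners, then 3R 7050001-7060000 with 35 and 214, 2R 12110001-12120000 with 32 and 209, and 3L 16370001-16380000 with 8 and 181. Also among the 5 bins with most heat-shock partners were X 9680001-9690000, with 75 partners in the companion list and 239 in the heat-shock list, and 3L 20530001-20540000, with 69 and 231. In the companion list, 2L 17980001-17990000 came second with 103 partners and had 113 in the heat-shock list. The remaining 3 of the 5 richest companion bins lay at the centromere end of 2R: 2R 140001-150000 had 100 partners in the companion list and 151 in the heat-shock list, 2R 10001-20000 had 81 and 98, and 2R 90001-100000 had 81 in each.

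Gains and losses were not adjusted for the greater length of the heat-shock list, which by itself favours gains. The largest loss was at 3L 24510001-24520000, from 57 partners in the companion list to 23 in the heat-shock list, followed by X 21020001-21030000 from 32 to 1. The bins 2L 8290001-8300000 (38 to 8), 3L 24320001-24330000 (43 to 13) and 3R 19150001-19160000 (32 to 2) each had 30 fewer partners.

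**Figure D2:**
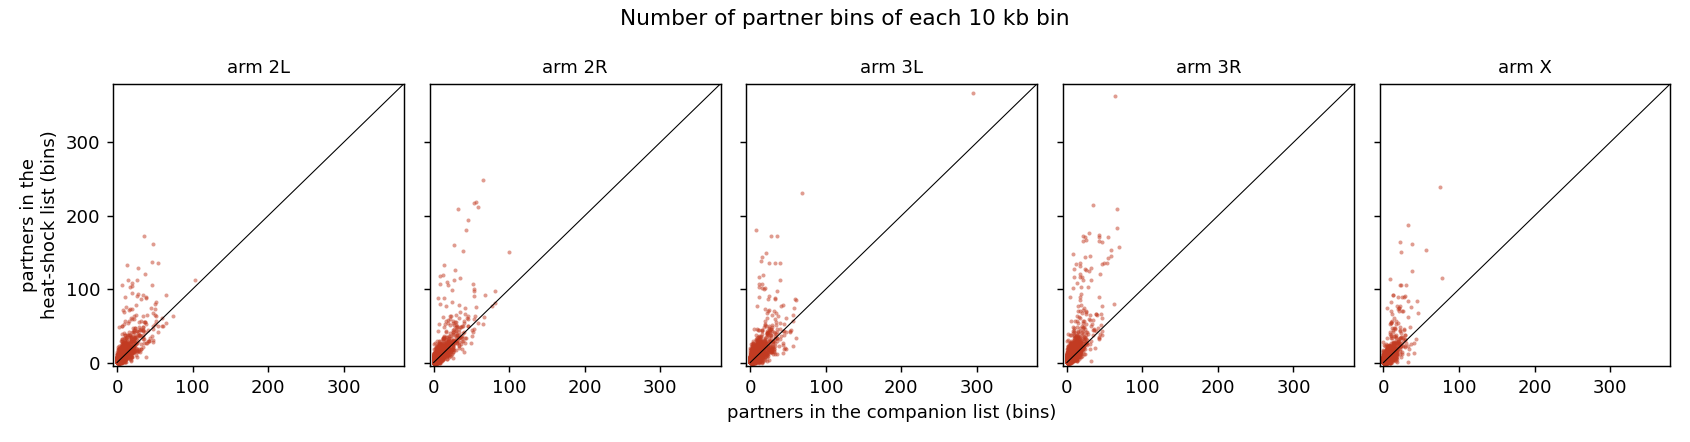
Number of different partner bins of each 10 kb bin in the companion list (x axis) and in the heat-shock list (y axis), 1 panel per chromosome arm; each point is a bin and the line marks equal numbers. Many bins lie far above the line, up to 363 against 64 partners at 3R 6970001-6980000, and 3L 24160001-24170000 is high in both lists.

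The fourth comparison set the chromosome arms side by side, including the X against the autosomes. Arm 3R had the largest relative increase, with 16151 pairs in the heat-shock list and 7711 in the companion list, a ratio of 2.09 (2.04 to 2.15). The ratio was 1.60 (1.55 to 1.65) on 2L, 1.66 (1.61 to 1.71) on 2R, 1.62 (1.58 to 1.67) on 3L and 1.72 (1.66 to 1.78) on X. The X ratio was 0.98 times that of the other arms (0.94 to 1.02), which is within the counting error. The X had the fewest pairs per Mb in both lists, 376 in the heat-shock list and 219 in the companion list. The 3R ratio was 1.27 times that of the other arms (1.24 to 1.32), and 1.08 times (1.04 to 1.12) once pairs that touched a top bin of either list were left out; 43 of the 112 heat-shock top bins and 22 of the 112 companion top bins lay on 3R, which holds 23.9% of the bins used. Without those pairs the 2L ratio moved from 0.90 to 1.02 times that of the other arms. Without the 1 Mb at the centromere end of each arm, the 3L ratio moved from 0.91 to 1.00 times that of the other arms and the 2R ratio from 0.94 to 0.98 (0.94 to 1.02).

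**Figure D3:**
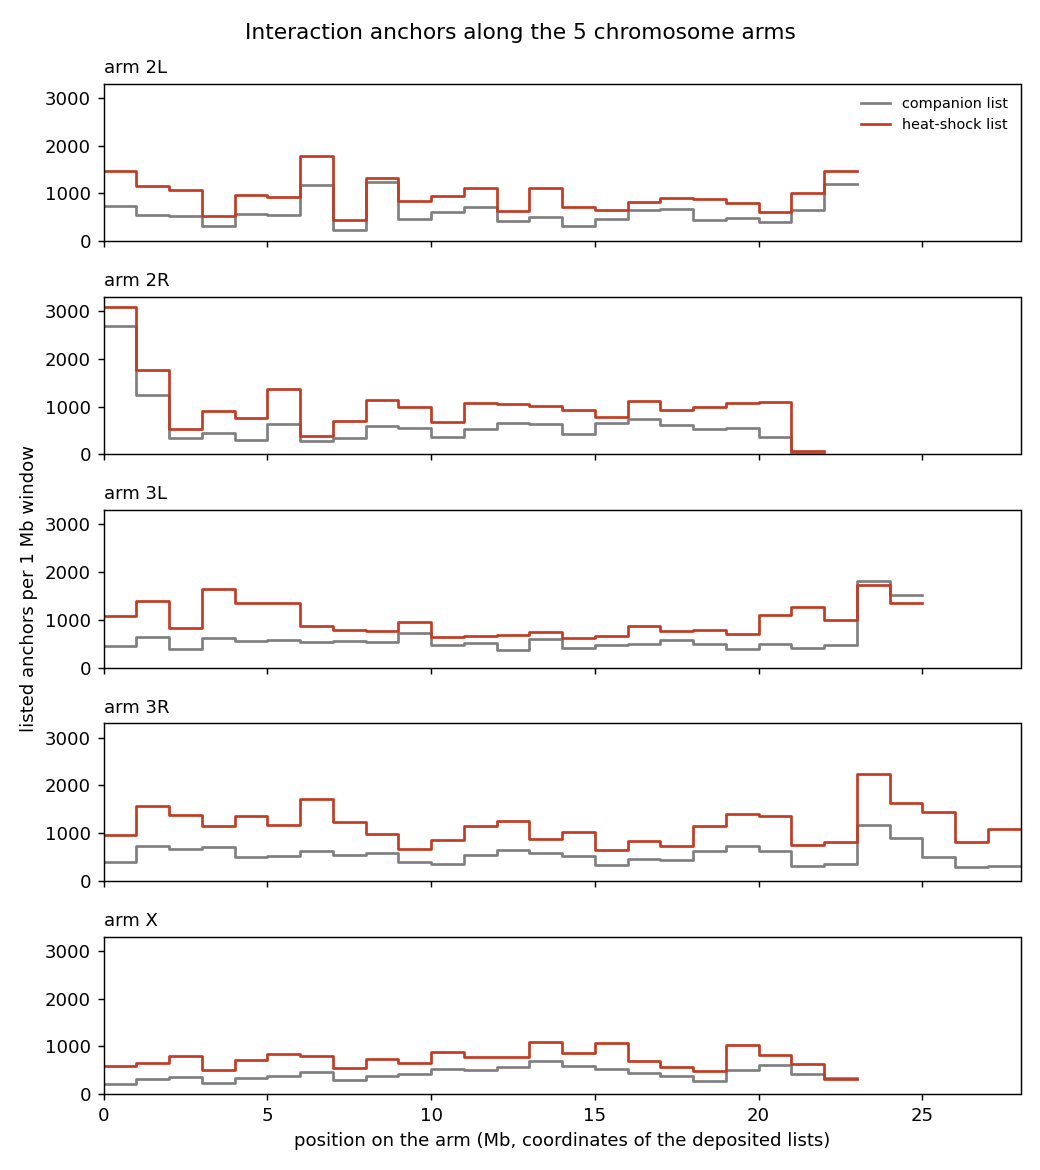
Listed anchors (ends of pairs) per 1 Mb window (y axis) along each chromosome arm (x axis, Mb in the coordinates of the deposited lists) in the companion list (grey) and the heat-shock list (red); the first and last windows of an arm can be partly empty. Of the 121 windows, 118 have more anchors in the heat-shock list, with a median ratio of 1.78, and the 3 exceptions are the last window of X and the last 2 windows of 3L.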

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

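The lists hold only the 5 main arms and no pairs of the same or adjacent bins, so leaving out other arms or near pairs changes nothing and is not given; gene lists and gene density were not run. The top-1%, centromere-end and partner-number alternatives were chosen after the data were seen. Of 82 alternative values, 32 stayed within the interval of the reported value (numbers of bins used, within 1.5 times) and 50 left it. At equal length the companion list is unchanged. Its median distance, share over 1 to 5 Mb and number of bins used could not move there but count among the 32. For observed over random, the interval was the wide range set by the highest and lowest rotation, 5.27 to 41.6. Of the arm ratios, 4 crossed 1: 1 each on 2L and 3L, and 2 on X, whose reported interval includes 1. The cause of each move was not tested unless the construction shows it.

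The order of the lists held in every distance alternative. The heat-shock and companion medians were 1.56 and 1.22 Mb in the stricter lists, 1.74 and 1.31 Mb without top bins, and 1.73 and 1.42 Mb without the centromere ends; at equal length the heat-shock median was 1.55 Mb. The heat-shock share over 1 to 5 Mb was 50.003% at equal length, 50.4% in the stricter list, 45.5% without top bins and 50.6% without the centromere ends, where the companion share was 40.1%.

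The shared part of the companion list was 51.0% within 1 bin, 62.0% within 2 bins, 23.7% at equal length, 24.5% without top bins and 29.9% without the centromere ends. Observed over random was 7.74 within 1 bin, 4.65 within 2 bins, 58.2 in the stricter lists and 2.35 against partner numbers. This ratio stayed above 1 throughout.

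The rank correlation of partner numbers across bins was 0.73 for 50 kb bins, 0.57 at equal length, 0.52 for partners over 1 Mb away, 0.47 in the stricter lists, 0.62 without top bins and 0.65 without the centromere ends. Pairs touching the top 1% of bins made up 9.0% (heat-shock) and 7.58% (companion) with 50 kb bins, 38% and 23.6% in the stricter lists, and 19.5% and 13.5% once the first top bins were removed. The companion value was 21.2% for partners over 1 Mb away; the heat-shock value was 36.6% at equal length, 26.9% with as many pairs drawn at random (an alternative chosen after the data were seen) and 28.7% without the centromere ends.

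Relative to the other arms, 3R was at 1.36 in the stricter lists, 1.08 without top bins and 1.18 without the centromere ends, above 1 in all. Arm 2L was at 0.86 at equal length, in the stricter lists and without the centromere ends, and crossed to 1.02 without top bins. Arm 3L was at 0.87 at equal length, 0.86 in the stricter lists, 0.97 without top bins, and crossed to 1.00 without the centromere ends. Arm 2R was at 0.97 in the stricter lists and 0.98 without the centromere ends, and X crossed to 1.03 at equal length and to 1.00 without top bins. Depth limits all of these: no counts accompany the lists, so absence from a list does not show absence of contact.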

Other observations

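The windows, sets of bins and sets of pairs below were chosen after the data were seen. The deciding bounds of the tests were set before they were computed.

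The ends of the arms differed between the lists. Coordinates of 2L, 3L and X end, and those of 2R and 3R begin, at the centromere. In the 1 Mb at the centromere end, where heterochromatin flanks the arm, pairs with at least 1 bin in the window numbered 6481 in the heat-shock list and 5264 in the companion list over the 5 arms, a ratio of 1.23 (1.19 to 1.28). In the 1 Mb at the telomere end they numbered 4637 and 1824, a ratio of 2.54 (2.41 to 2.69). The whole lists had a ratio of 1.75. At the centromere end the ratio was 0.93 (0.87 to 1.0) on 3L, 1.05 (0.91 to 1.21) on X, 1.26 (1.18 to 1.33) on 2R and 1.39 (1.27 to 1.52) on 2L, but 2.52 (2.22 to 2.87) on 3R. At the telomere end it was 2.0 (1.82 to 2.21) on 2L, 2.24 (2.0 to 2.51) on 3L, 2.71 (2.29 to 3.23) on X, 3.20 (2.80 to 3.67) on 2R and 3.44 (3.0 to 3.94) on 3R.

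Pairs with both bins inside the centromere-end windows numbered 1755 in the heat-shock list and 2075 in the companion list, a ratio of 0.85 (0.79 to 0.90), although the heat-shock list was the longer. By arm this ratio was 0.60 (0.53 to 0.69) on 3L, 0.87 (0.75 to 1.02) on 2L, 0.90 (0.81 to 0.99) on 2R, 1.04 (0.85 to 1.27) on X and 2.14 (1.52 to 3.06) on 3R. Inside the telomere-end windows the numbers were 861 and 331, a ratio of 2.60 (2.29 to 2.96). With the bins in the top 1% left out, pairs touching the windows had a ratio of 1.31 (1.25 to 1.38) at the centromere ends, 2.17 (2.04 to 2.31) at the telomere ends and 1.5 (1.47 to 1.52) over whole arms. In lists of equal length the ratios were 0.78 (0.75 to 0.81) and 1.48 (1.4 to 1.57). In 1 Mb windows on 3L the ratio was 3.08 at 21 to 22 Mb, near the centromere end, and 0.96 and 0.89 in the windows from 23 Mb on. Neither a trend along the arms nor an explanation for these differences was tested.

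The larger share of pairs over 1 to 5 Mb apart in the heat-shock list was not carried by the weaker pairs that make this list longer. Among its strongest pairs, as many as the companion list holds, that share was 50.003%, which is 13.4 percentage points above the companion list. Nor did it come only from a few bins that take many pairs. Without the bins in the top 1% the difference was 8.41 points, down from 11.3. Among the pairs left out the share was 52.3% in the heat-shock list and 34.9% in the companion list, a wider gap. The cut by score also raised the share of heat-shock pairs that touch top bins, from 27.2% to 36.6%. Length and top bins were left out 1 at a time and never together, so what they account for jointly is not known. A difference in library depth, in the number of libraries pooled or in the background model behind the scores stays open, because the lists carry no counts. An effect of heat shock stays open as well and could not be tested, since no label gives the treatment behind the companion list.

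The bins that gained most partners stood alone. The 50 bins with the largest gain had a median of 30 partners in the companion list and 166 in the heat-shock list, a median gain of 132.5. The 98 bins beside them had a median gain of 1, a ratio of 0.00755 to that of the 50, and none gained more than 19. All bins used had a median gain of 2. At equal list length the median gain of these bins was 100. By the bound set beforehand this counted against list length, but that test was set aside after its result was seen: plain thinning of bins picked for their gain would leave 63.2, so it decides nothing on list length. Random draws of as many heat-shock pairs as the companion list holds were added after the data were seen. In them 26.9% of pairs (26.3 to 27.3%) touched the top 1% of bins, against 17.5% in the companion list in the same comparison. Drawing at random keeps the share almost as it was (27.2%) by construction, so the draws do not decide whether list length made it larger. They also cannot show what a difference in depth would do, and they do not test the gain of the 50 bins. A candidate explanation is a property of the single bin, such as its restriction fragments, its mappability or its copy number in the heat-shock libraries. Contacts of a region wider than 1 bin would also be expected in adjacent bins. Companion top bins also had more partners than the bins beside them (median 52 against 8), so standing alone is not particular to bins that gained. To make a gain, a property of the single bin would have to act differently in the 2 lists. How the companion list was prepared is not known. A short element that gains contacts after heat shock was not tested and stays open. These bins touched 14.5% of heat-shock pairs, 22 of the 50 lay on 3R, and only 1 pair joined 2 of them.

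The strongest distant pairs were only partly the same in both lists. Of the 100 strongest companion pairs over 5 Mb apart, 52% (41.8 to 62.1%) were in the heat-shock list, against 11.2% of all companion pairs at that distance. Of the 100 strongest heat-shock pairs over 5 Mb apart, 83% were in the companion list, against 6.56% of all heat-shock pairs at that distance. A join of distant sequence, as from a rearrangement carried by the line or an error of the assembly, may account for pairs that are extreme in both lists. The 52% of companion pairs met the bound of at least 50% set for it beforehand, a bound that took no account of an interval. The interval reaches below 50% and treats pairs as independent, so the result was left undecided. Of the 48 companion pairs that were missing, 37 had no heat-shock pair within 5 bins of both anchors. The depth is unknown, and so are the cells behind the companion list, so a join in one list need not be in the other. These missing pairs therefore do not decide on a join either. The median number of other companion pairs within 5 bins of both anchors was 2, between the bounds set for and against repeated sequence shared by single bins, so that explanation stays open too.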
